A study of Mus musculus with 26 samples.

How the data were processed

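RNA-seq and RNA polymerase II HiChIP of mouse E14 cells, labelled as taken after 12 days of neural induction, were analysed, WT-labelled and Klf4-KO-labelled, with 2 samples per assay and genotype. ESCs had been grown on gelatin with serum, LIF and inhibitors of MEK and GSK3, per the labels' protocols. The series design states 2 biological replicates per condition, and p-values measure the spread between those. Groups were taken from the sample titles. The ChIP-seq samples of ESCs were not analysed here.

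The RNA-seq files hold raw counts per gene symbol as deposited by the authors, 1 file per library, not normalized. HISAT2 2.1.0, featureCounts 2.0.3 and DESeq2 1.18.1 stand among the tools in the submitters' processing notes, with the build mm10. The closing rows of each file have the form that htseq-count writes, so the counter is not settled, and its annotation and strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. The 5 rows that name no gene stayed out of library sizes and tests. Reads without a feature made up 6.16% and 6.05% of the column totals in WT-labelled libraries and 8.07% and 8.00% in KO-labelled ones. Ambiguous reads made up 4.19% to 4.41%, reads without a unique alignment 7.06% to 7.69%, unaligned reads 1.07% to 1.61% and reads of low alignment quality 1.03% to 1.51%. Mitochondrially encoded genes took 2.11% to 2.32% of gene counts. A count of 3 corresponded to 0.0837 to 0.108 CPM.

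The HiChIP files are loop lists without a header, deposited by the authors, 1 per genotype and named in the labels of both replicates, so replicates appear pooled. Each row gives both anchors, a count of paired-end tags and a false discovery rate (a q-value between 0 and 1), both the authors' values. Bowtie2 2.4.4, HiC-Pro 2.11.1 and MACS2 2.2.7.1 stand in the submitters' processing notes. The processing notes state no loop caller, though the names of the deposited lists hold the word mango. All loops lay within 1 chromosome and joined anchor centres 5.00 kb to 2000 kb apart, and 58.7% of WT-labelled and 65.6% of KO-labelled loops had 1 tag. Because anchors were called in each list separately, sums of tags depend on how much was called, and covered length is given beside them.

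Genes were filtered with filterByExpr, scaled with TMM (factors 0.931 and 0.928 for WT-labelled, 1.075 and 1.076 for KO-labelled libraries) and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest, two-sided). P-values were adjusted by Benjamini-Hochberg over 17273 genes, of 52535 rows. CPM values use TMM-scaled library sizes. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Where all libraries of a group had 0 counts, a lower bound of the fold was computed against 3 counts per library. Where they had 1 to 3 in total, the ratio of counts was given with an exact binomial 95% interval. Such intervals and floors cover counting error only. Each library was counted as 1 biological replicate, as the series design states.

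A total of 26 gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, log CPM with a prior count of 2), adjusted over lists. None of the 16 lists that passed did so with an estimated correlation, where the lowest adjusted p was 0.228. With 2 libraries per genotype, that version rests on few residual degrees of freedom and had little power to call a list. Its estimates were negative for lists such as Hox (-0.165) and pluripotency (-0.0122), and positive for others such as primed epiblast (0.214). Its adjusted p-values, given beside the sets, neither support nor undo the calls. Genes were named by this rule: Klf4; in each list the 2 called members with the largest rise and the 2 with the largest fall; over all genes the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and at least 5 CPM in the higher group, unnamed gene models left out. Some results that this rule and the alternatives give are not reported here. With 2 libraries against 2, chance alone puts groups apart in 1 of 3 genes. For loops the rule named Klf4, Sox2, Pax6, Nes, Pou5f1 and Nanog and, among list genes with at least 20 tags, the 5 largest and 5 smallest tag-share ratios. Values printed for Pax6, Sox2, Nes, Pou5f1, Nanog, Cspg4 and Sox10 in RNA-seq follow that loop rule.

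Loops were kept at an FDR of at most 0.01 and at least 2 tags. A loop was shared where both anchors overlapped both anchors of a loop of the other list by at least 1 base. Shares carry Clopper-Pearson 95% intervals and medians an order-statistic interval. Gene coordinates came from the RefSeq table of GRCm38.p6, the assembly of mm10. The table used here has no strand, so the planned window around transcription starts was replaced by 2500 bases around either annotated end of a gene. Of the genes tested, 15986 (92.5%) had coordinates, by symbol or a unique older symbol, as had 694 of 694 list entries, Spink1 and Spink3 of the endoderm list pointing to 1 gene. The log2 ratio of tag shares used a pseudocount of 0.5 tags and genes with at least 10 tags over both lists. Random lists were matched in 20 bins of mean tags. A permutation p had been planned for the correlation of tag ratio and expression. It is left out because genes are not replicates and each genotype has 1 loop list. Loops were handled in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1.

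Both procedures were tested on simulated data. In counts simulated for the RNA-seq comparison, with 200 changed genes among 15662 tested, edgeR recovered 27 of 50 genes changed 1.25-fold, 38 of 50 changed 1.5-fold, 43 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 8 false calls among 166. As many of the 200 genes rose as fell, whereas 73.1% of genes tested were called in the data. These rates therefore need not hold for the data, and scaling under so many changes was not tried. In simulated loop lists of 2849 and 1900 loops, all 950 shared loops were found. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, the replicate number as a block, a test against a 1.5-fold change, leaving out each library, other set tests, and other limits on loop FDR, tags, distance, overlap, window and depth.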

Results

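The series profiled E14 cells, a mouse embryonic stem cell (ESC) line, with and without a knockout (KO) of Klf4, a zinc-finger transcription factor of the naive pluripotency network. Its title names KLF4, early neural differentiation and 3D chromatin structure. Of the 26 samples, 4 were RNA-seq libraries labelled as neural progenitor cell (NPC) cultures after 12 days of neural induction, with 2 biological replicates per genotype. Another 4 were RNA polymerase II HiChIP samples of the same stage, an assay that enriches pairs of distant DNA fragments held together at sites bound by the polymerase. HiChIP was deposited as 1 loop list per genotype. The ChIP-seq samples of undifferentiated ESCs (H3K27ac, H3K27me3, H3K4me1 and their inputs) were not analysed here. Gene counts totalled 37703866 and 29835774 in the WT-labelled RNA-seq libraries and 31909094 and 33347088 in the KO-labelled ones. The loop lists held 407150 tags (WT-labelled) and 977208 tags (KO-labelled).

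The targeted gene was read first. Klf4 (mm10, chromosome 4, 55527137 to 55532475) had 0 counts in WT replicate 1 and 0 in WT replicate 2. It had 2571 counts in KO replicate 1 and 2538 in KO replicate 2, or 72.9 ± 2.98 CPM (counts scaled to library size, ± SD, n = 2). Klf4 was at least 752-fold higher in the KO-labelled libraries, taking a floor of 3 counts per library for WT (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.25e-23). This is the opposite of what the genotype labels state. Libraries are therefore named by their label throughout, and every direction given for expression is KO-labelled over WT-labelled, with the true genotype of the RNA-seq libraries left open. Among the 21 KLF and Sp family genes tested, 12 were higher and 6 lower in the KO-labelled libraries. Sp8 rose by 3.33 ± 0.40 (log2, SE), while Klf5 fell by 1.63 ± 0.051 and Klf8 fell by 1.48 ± 0.065. As a set the family did not pass (camera adjusted p = 0.137).

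Expression separated the labelled genotypes widely. The largest rises in KO-labelled libraries were in Klf4 and in genes of contractile and matrix proteins. Acta2, smooth-muscle actin, had 1 and 0 counts in WT-labelled libraries against 150 ± 3.49 CPM (SD, n = 2). Its count ratio was 9412, with a counting interval of 1689 to 371774. Col1a2, a chain of type I collagen, had 1 and 1 counts against 146 ± 3.80 CPM (ratio 4593, interval 1271 to 37927). No WT-labelled library had a count for Acta1, Prss23, Lhx1, Pcdh7, Bgn or Actc1. These were at least 209-, 205-, 185-, 104-, 72.6- and 71.4-fold higher, in that order. The largest falls were in Halr1 (13.0 ± 1.56 CPM in WT-labelled libraries, 0 and 1 counts in KO-labelled ones, count ratio 902, interval 161 to 35655), Cidea, a lipid-droplet protein (21.9 ± 2.97 CPM against 0 and 2 counts, ratio 775, interval 214 to 6409), Eif4e1b (ratio 654, interval 117 to 25859) and Stra8, a retinoic-acid-responsive gene of germ cells (ratio 474, interval 84.6 to 18754). Cdx1, a caudal-type homeobox gene and Wnt target, fell by 7.92 ± 0.19. Myo1f fell by 8.27 ± 0.24, Accsl fell by 6.69 ± 0.18, Smtnl1 fell by 6.53 ± 0.31 and Efhc2 fell by 6.22 ± 0.12 (log2, SE). All these genes had edgeR adjusted p-values between 2.13e-27 and 3.54e-13.

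Over 17273 genes tested, 6428 were higher and 6190 lower in the KO-labelled libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Together 73.1% of genes tested were called, and counts of called list members are to be read against that share. Adjusting over a list alone uses the same p-values and is not a second test. Changes of at least 2-fold were more often rises, with 3856 genes against 1962. Replicates correlated at r = 0.988 (WT-labelled) and 0.990 (KO-labelled) on log CPM, and libraries of different labels at 0.878 to 0.881. The share of called genes that were higher was 50.9% with TMM factors and 62.0% with library size alone, a scaling that moved the median log2 fold change up by 0.21. Genes of ribosomal proteins took 8.13% and 8.15% of counts in WT-labelled and 9.73% and 9.90% in KO-labelled libraries.

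Pluripotency genes had high counts in both labelled genotypes, although the labels call the libraries neural progenitors at day 12. Of 34 naive and core pluripotency genes, 31 stood at 20 CPM or more in both labelled genotypes. This argues against cultures that had left pluripotency as a whole. What share of the cells had left it is open, and the neural values given here stand beside that. Pou5f1, the core pluripotency factor also known as Oct4, stood at 841 CPM in WT-labelled and 430 CPM in KO-labelled libraries. Nanog stood at 1140 and 407 CPM. Of 34 naive and core pluripotency genes tested, 25 were lower and 9 higher in the KO-labelled libraries, and the counts adjusted over the list alone were 25 and 9. The largest falls were in Tbx3, which fell by 3.40 ± 0.053 from 288 to 27.3 CPM, and Tfcp2l1, which fell by 2.92 ± 0.028 from 1018 to 135 CPM. Both belong to the naive network. The largest rises were in Dppa3 (2.12 ± 0.084) and Lefty1, a Nodal antagonist (1.86 ± 0.061). The list was lower as a set (camera adjusted p = 0.00211; adjusted p = 0.228 with an estimated correlation).

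Primed epiblast genes were higher in KO-labelled libraries as a set (camera adjusted p = 0.00119; adjusted p = 0.292 with an estimated correlation). Of 17 tested, 14 rose and 2 fell, and 14 and 2 when adjusted over the list alone. Cer1, a secreted Nodal, BMP and Wnt antagonist, had 1 and 0 counts in WT-labelled libraries and 27.6 ± 1.72 CPM in KO-labelled ones (ratio 1733, interval 311 to 68479). Fgf8 had 2 and 0 counts against 11.1 ± 1.85 CPM (ratio 350, interval 96.4 to 2891). Nkx1-2 fell by 5.43 ± 0.14. Foxd3 fell by 0.20 ± 0.077, a call lost with upper-quartile factors and without WT replicate 1 or KO replicate 1, and with library size alone its log2 change was 0.0060.

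**Figure D1:**
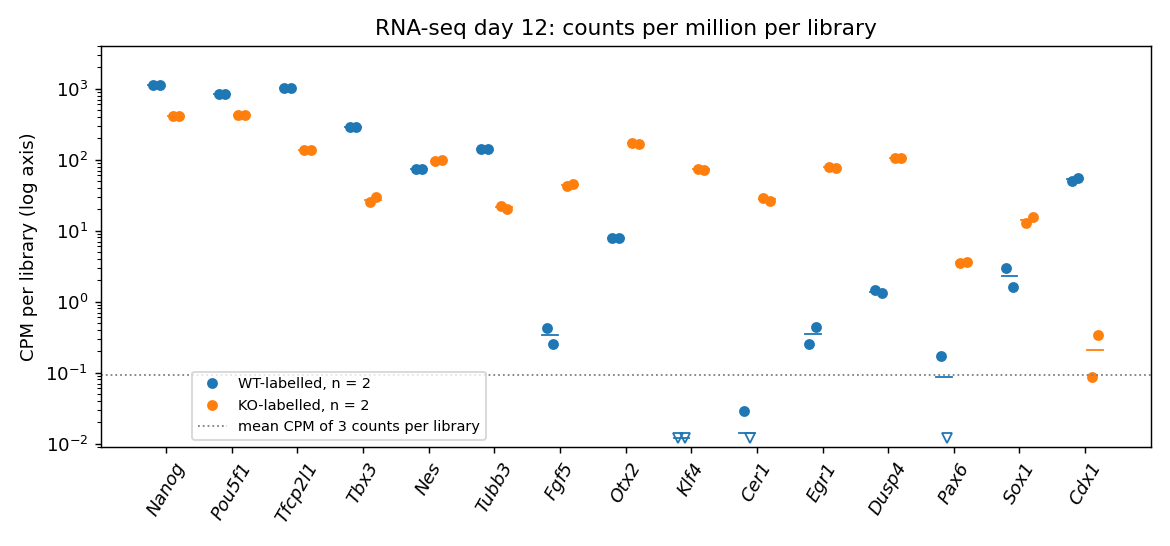
CPM (log axis) of 15 genes in each of the 4 RNA-seq libraries; filled points are libraries, short lines the mean of 2 libraries, open triangles libraries with 0 counts drawn at the bottom, and the dotted line the mean CPM of 3 counts. Klf4 has 0 counts in both WT-labelled libraries and a mean of 72.9 CPM in the KO-labelled ones, while Nanog stands at a mean of 1140 and 407 CPM.

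Neural progenitor genes were higher in KO-labelled libraries as a set (camera adjusted p = 0.00259; adjusted p = 0.228 with an estimated correlation). Of 33 tested, 25 rose and 5 fell, and likewise 25 and 5 adjusted over the list alone. Pax6, a neuroectodermal transcription factor, averaged 3.56 CPM in KO-labelled libraries, and Zic1 rose by 5.21 ± 0.55 to 3.64 ± 0.57 CPM. Fabp7, a radial glial fatty-acid binding protein, had 0 counts in both WT-labelled libraries and was at least 7.81-fold higher. Vim, the intermediate filament vimentin, fell by 1.85 ± 0.027, and Dach1 fell by 2.70 ± 0.17. Sox2 averaged 536 CPM in WT-labelled and 456 CPM in KO-labelled libraries, and Nes 73.3 and 96.6 CPM. Summed over the tested members, mean CPM was 2116 in WT-labelled and 1977 in KO-labelled libraries, so the list did not rise in total.

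Regional neural genes moved in different directions. Of 17 forebrain and midbrain genes tested, 16 rose and 0 fell (camera adjusted p = 5.11e-05; adjusted p = 0.228 with an estimated correlation), 16 of them also adjusted over the list alone. Fezf2 and Six6, with 0 counts in WT-labelled libraries, were at least 28.2- and 15.8-fold higher, at 2.74 ± 0.034 and 1.53 ± 0.23 CPM. Of 17 hindbrain and spinal cord genes, 13 rose and 3 fell (camera adjusted p = 0.0132; adjusted p = 0.228 with an estimated correlation), also 13 and 3 adjusted over the list alone. Lhx1 and Egr2 were at least 185- and 28.3-fold higher. Gbx2, an anterior hindbrain homeobox gene, fell by 3.71 ± 0.17 and Nkx6-2 fell by 3.59 ± 0.35. All 7 Hox genes tested fell, among them Hoxb13 (2.24 ± 0.71 CPM against 0 and 1 counts, ratio 153, interval 27 to 6089) and Hoxc12 (2.17 ± 0.76 CPM against 1 and 1 counts, ratio 78.2, interval 21.2 to 652), and all 7 did when adjusted over the list alone. The Hox set passed with all libraries (camera adjusted p = 0.00633; adjusted p = 0.228 with an estimated correlation) but not without WT replicate 1 (0.205), WT replicate 2 (0.119) or KO replicate 1 (0.0798).

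Of 37 neuronal genes tested, 24 rose and 7 fell (24 and 8 adjusted over the list alone). The set was higher (camera adjusted p = 0.0228; adjusted p = 0.228 with an estimated correlation), with an adjusted p of 0.0525 without KO replicate 1. Syt1, a synaptic vesicle calcium sensor, had 3 and 0 counts in WT-labelled libraries and 3.12 ± 1.35 CPM in KO-labelled ones (ratio 65.6, interval 22.2 to 321), and Robo2 had 0 and 3 counts against 2.29 ± 0.51 CPM (ratio 48.0, interval 16.1 to 235). Tubb3, the neuronal beta-tubulin, went the other way and fell by 2.73 ± 0.057 from 141 to 21.3 CPM, and Ebf1 fell by 1.72 ± 0.26. Of 19 astrocyte and oligodendrocyte genes, 14 rose and 3 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.0311; adjusted p = 0.261 with an estimated correlation). The glutamate transporter Slc1a2 was at least 8.66-fold higher and Nfia rose to 0.674 ± 0.24 CPM (ratio 21.0, interval 5.51 to 179), while Nfib fell by 2.37 ± 0.12 and Sparcl1 fell by 1.38 ± 0.49, a call lost without KO replicate 1.

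Markers of other lineages rose with these neural genes in the KO-labelled libraries. Of 21 fibroblast and extracellular matrix genes tested, 18 rose and 2 fell, with a median log2 fold change of 3.50, or 2.89 with genes at 0 in WT-labelled libraries set to their bounds (camera adjusted p = 2.92e-05; adjusted p = 0.228 with an estimated correlation). Bgn, a matrix proteoglycan, rose and Timp1 and Sparc fell (by 1.31 ± 0.10 and 0.80 ± 0.030). Of 28 mesoderm and muscle genes, 22 rose and 1, the atrial myosin light chain Myl7, fell by 1.48 ± 0.20 (camera adjusted p = 5.11e-05; adjusted p = 0.228 with an estimated correlation). Of 26 endoderm genes, 21 rose and 4 fell (camera adjusted p = 0.00302; adjusted p = 0.228 with an estimated correlation). Sox17 rose by 6.14 ± 0.33 to 11.4 ± 1.11 CPM and Shh reached 2.75 ± 0.92 CPM (ratio 174, interval 30.8 to 6893), whereas Apom fell by 3.89 ± 0.33 and Cdx2 fell by 3.33 ± 0.22. In these 3 lists the counts adjusted over the list alone were also 18 and 2, 22 and 1, and 21 and 4. Of 21 neural crest and non-neural ectoderm genes, 13 rose and 6 fell, as adjusted over the list alone. Pax3 and Tfap2b were at least 20.1- and 6.90-fold higher, and Ngfr and Mitf fell by 3.93 ± 0.13 and 2.96 ± 0.093. That set passed with all libraries (camera adjusted p = 0.0424; adjusted p = 0.267 with an estimated correlation) but not with the replicate block (0.0515) or without KO replicate 1 (0.0637) or 2 (0.0523).

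The trophoblast and endothelial lists did not pass as sets (camera adjusted p = 0.195 and 0.0764). Of 11 trophoblast genes tested, 7 rose and 4 fell, unaltered when adjusted over the list alone. The simple-epithelium keratins Krt18 and Krt8 rose by 5.70 ± 0.083 and 4.70 ± 0.059, to 192 and 201 CPM, and Gcm1 fell by 3.14 ± 0.88, a call lost without WT replicate 2, KO replicate 1 or KO replicate 2. Of 12 endothelial and blood genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone). Tie1 was at least 25.6-fold higher and Flt1, a VEGF receptor, rose by 6.85 ± 0.18 to 38.9 ± 0.73 CPM, while Eng fell by 1.49 ± 0.073 and Pecam1 fell by 0.43 ± 0.050. Without WT replicate 1 or 2 this set passed (0.0346 and 0.0130).

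Signalling genes also differed. Of 20 FGF and ERK feedback genes tested, 15 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.00632; adjusted p = 0.228 with an estimated correlation). Egr1, an immediate-early gene induced by ERK, rose by 7.86 ± 0.14 from 0.345 ± 0.13 to 78.4 ± 2.25 CPM. Dusp4, an ERK phosphatase, rose by 6.26 ± 0.096 from 1.38 ± 0.11 to 107 ± 0.12 CPM. Etv4 and Etv1 fell by 1.06 ± 0.094 and 0.89 ± 0.12. Wnt targets went both ways and did not pass as a set (camera adjusted p = 0.404), with 8 of 20 higher and 11 lower on either adjustment, the second over the list alone. Nkd2 and Nkd1 rose by 5.17 ± 0.37 and 3.11 ± 0.25, whereas Cdx1 and Wif1, a Wnt inhibitor, fell. Wif1 fell by 3.92 ± 0.65, a call lost with DESeq2. Of 20 BMP and TGF-beta targets, 13 rose and 5 fell, as adjusted over the list alone. Msx1 rose by 5.63 ± 0.53, and Msx2 and Smad7 fell by 3.06 ± 0.22 and 1.06 ± 0.046. This set had a camera adjusted p of 0.0325 (adjusted p = 0.267 with an estimated correlation), which became 0.0606 with the replicate block, 0.0526 without WT replicate 2, 0.0525 without KO replicate 1 and 0.0522 without KO replicate 2. Of 18 Notch genes, 12 rose and 3 fell on both adjustments, over all genes and adjusted over the list alone. The ligands Dll4 (count ratio 21.5, interval 3.50 to 883) and Dll1 (2.95 ± 0.27) rose, and Cdkn1c and Jag1 fell by 1.10 ± 0.20 and 0.95 ± 0.075. The Notch set passed (camera adjusted p = 0.0311; adjusted p = 0.292 with an estimated correlation), but not without KO replicate 1 (0.0525) or 2 (0.0523), and the call of Dll4 was lost without WT replicate 2.

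**Figure D2:**
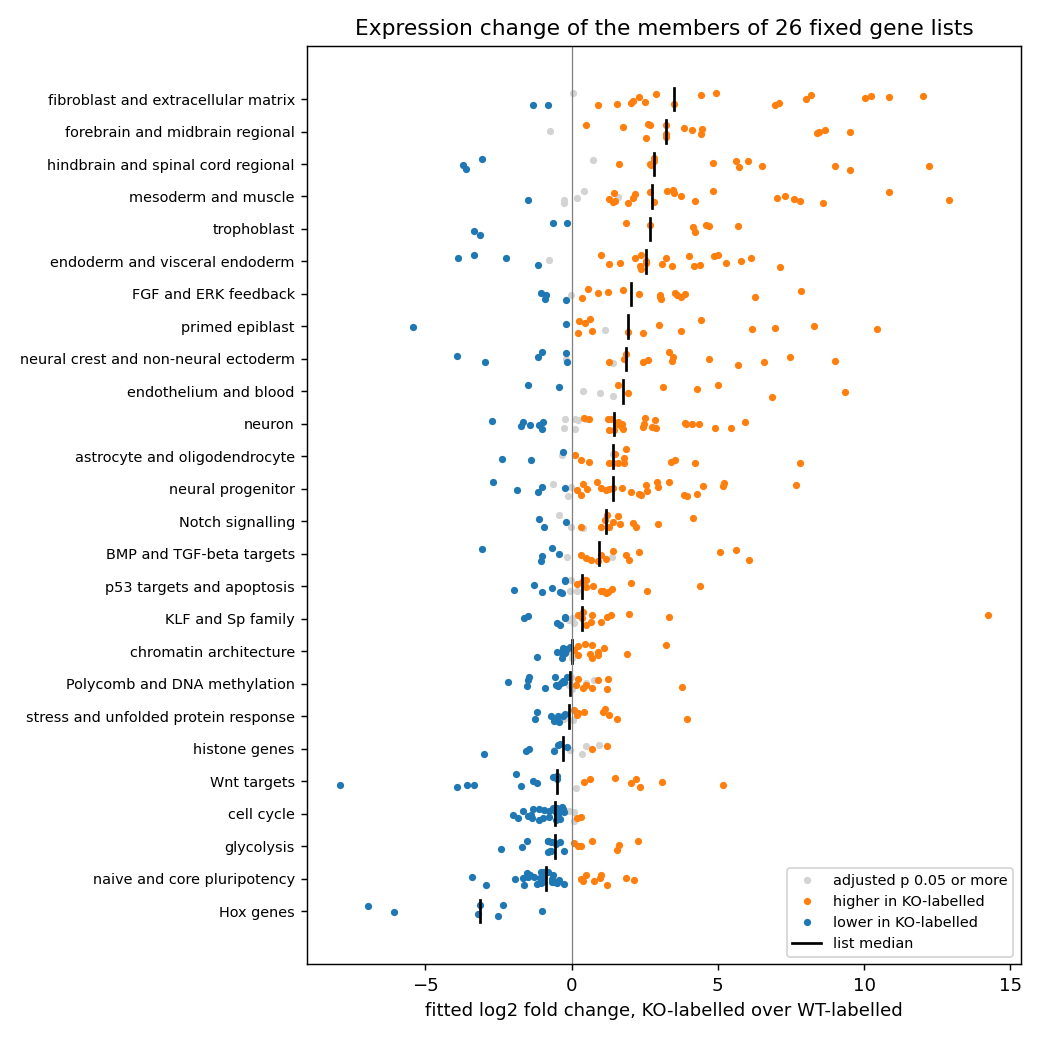
Fitted log2 fold change (KO-labelled over WT-labelled, x axis) of each tested member of the 26 gene lists, ordered by list median (black line); orange points were higher and blue points lower at an edgeR adjusted p below 0.05, and gray points were not called. The Hox and pluripotency lists lie lowest, with medians of -3.15 and -0.88, and the fibroblast and matrix list highest, with 3.50; with genes at 0 counts set to their bounds its median is 2.89, below the forebrain and midbrain list at 3.23.

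Cell cycle genes were lower in the KO-labelled libraries as a set. Of 32 cell cycle genes tested, 26 fell and 2 rose (26 and 3 adjusted over the list alone; camera adjusted p = 2.81e-05; adjusted p = 0.228 with an estimated correlation). Cyclin E1 (Ccne1) fell by 2.01 ± 0.041 and Aurka, a mitotic kinase, fell by 1.84 ± 0.033, while Mki67 and Foxm1 rose by 0.32 ± 0.031 and 0.20 ± 0.051. Of 20 glycolysis genes, 13 fell and 7 rose, the same as adjusted over the list alone, without passing as a set (camera adjusted p = 0.0721). Hk2, a hexokinase, and Ldha, lactate dehydrogenase A, fell by 2.41 ± 0.038 and 1.71 ± 0.022, whereas Pdk1, which inhibits pyruvate dehydrogenase, rose by 2.26 ± 0.036 and Eno2 rose by 1.64 ± 0.13. Of 25 p53 target and apoptosis genes, 14 rose and 8 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.369). Trp53 itself fell by 1.96 ± 0.031 and Sesn1 fell by 1.27 ± 0.081, while Bcl2 rose by 4.38 ± 0.63, a call lost with DESeq2, and Fas rose by 2.59 ± 0.81, a call lost without KO replicate 1. Stress genes divided evenly, 9 higher and 9 lower of 20 on both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.654). Atf3 rose by 3.95 ± 0.20 and Hspa1a rose by 1.56 ± 0.39, a call lost without KO replicate 1. Asns fell from 774 to 325 CPM and Hsph1 fell by 1.20 ± 0.032. The list median was -0.079, in the direction of the set test, and the mean 0.20.

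Chromatin genes did not move as sets. Of 26 chromatin architecture genes, 12 rose and 9 fell (camera adjusted p = 0.444), and of 26 Polycomb and DNA methylation genes, 9 rose and 12 fell (camera adjusted p = 0.451), with the same counts adjusted over the list alone. For the Polycomb list the median was -0.046, the direction of the set test, and the mean 0.0024. Satb1 rose by 3.24 ± 0.16 and Lmna, which encodes lamins A and C, rose by 1.88 ± 0.097. Polr2a, the largest subunit of RNA polymerase II, fell from 454 to 200 CPM and Lmnb1 fell by 0.52 ± 0.026. Phf19 and Ring1, of the Polycomb complexes, rose by 3.78 ± 0.16 and 1.23 ± 0.12, and Tet2 and Eed fell by 2.17 ± 0.051 and 1.53 ± 0.036. Of 14 histone genes tested, 2 rose and 7 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.422). H1f0 rose by 1.21 ± 0.049 and Hist1h1c rose by 0.71 ± 0.18. Hist1h2bk fell by 3.01 ± 0.76 and Hist1h3a fell by 1.58 ± 0.70, the latter a call lost in 9 settings: DESeq2, upper-quartile factors, library size alone, no filter on low counts, the replicate block, a tested fold of 1.5, and without WT replicate 1, KO replicate 1 or KO replicate 2. Near-identical histone copies share reads, so the values of single histone genes are uncertain.

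Polymerase II loops were compared between the loop lists, with the genome structure named in the title as the question. Pluripotency genes such as Nanog and Pou5f1 held 481 and 416 tags in the WT-labelled list and 0 in the KO-labelled one, and Nes, Col5a1 and Sox10 held theirs in the KO-labelled list. Each genotype has 1 list, so there was no replicate error and no test between genotypes, and every interval on tags or loops covers counting error only. With a false discovery rate (FDR) of at most 0.01 and at least 2 tags, the WT-labelled list held 22148 loops with 175142 tags and the KO-labelled list 57463 loops with 285890 tags. Their anchors covered 61.6 and 115 Mb, or 2.84 and 2.49 tags per kb of anchor. Loops of the WT-labelled list carried a mean of 7.91 tags and those of the KO-labelled list 4.98. At least 5 tags were carried by 30.4% (29.7 to 31.0, Clopper-Pearson 95% interval) and 22.3% (21.9 to 22.6). Median loop length was 354 kb (350 to 358) in the WT-labelled and 305 kb (304 to 307) in the KO-labelled list. The limits set this length: it was 107 and 92.1 kb without an FDR limit, and 83.5 and 46.6 kb with at least 5 tags. With the KO-labelled tags thinned to the deposited WT-labelled total of 407150, 23124 loops with 97962 tags passed the same cut-offs in the KO-labelled list. They had a median length of 207 kb, a mean of 4.24 tags and 29.9% (29.3 to 30.5) with at least 5 tags. Thinning changed the tags alone, and each loop kept the FDR called from the full KO-labelled list. The thinned values are therefore not fully matched to the WT-labelled list in depth.

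Under these limits few loops joined the same places in both lists. Of the WT-labelled loops, 2609 (11.8%, 11.4 to 12.2) had a KO-labelled loop overlapping both anchors, and of the KO-labelled loops 2773 (4.83%, 4.65 to 5.00) had a WT-labelled one. Among loops of at least 10 tags the shares were 15.6% (14.6 to 16.7) and 7.89% (7.32 to 8.48). Without an FDR limit 23.7% of WT-labelled and 8.77% of KO-labelled loops were shared, and among those of at least 10 tags 37.2% and 21.7%. Single anchors were shared more often, with 51.5% of 13073 WT-labelled anchors meeting a KO-labelled anchor and 23.8% of 28990 KO-labelled anchors meeting a WT-labelled one. With thinned KO-labelled tags, whose loops kept the FDR of the full list, 6.22% (5.90 to 6.54) of WT-labelled loops were shared.

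At individual genes the lists differed at several pluripotency loci. Pou5f1 (mm10, chromosome 17, 35506032 to 35510777) had 416 tags in the WT-labelled list and 0 in the KO-labelled list, at least 226-fold fewer by share of tags against a floor of 3 tags. Nanog (chromosome 6, 122707489 to 122714633) had 481 and 0 tags, at least 262-fold fewer. These bounds hold for the settings used: with a window of 10000 bases the log2 ratio of tag shares was -5.89 at Pou5f1 and -5.80 at Nanog, and without an FDR limit it was -6.08 at Nanog. Rbpj, the Notch transcription factor, had 394 and 0 tags, Trim71 340 and 0, and Spp1 237 and 0. With windows over whole genes the log2 ratio was -5.40 at Rbpj and -6.54 at Trim71, and with 10000 bases it was -6.77 at Trim71. Without an FDR limit the KO-labelled list held 16 tags at Nanog, 17 at Trim71 and 0 at Pou5f1, Rbpj and Spp1. Sox2 (chromosome 3, 34649995 to 34652461) had 217 and 174 tags, so that the KO-labelled share was 0.491 of the WT-labelled one (0.400 to 0.602). Over all genes with at least 10 tags the median log2 ratio was 1.01, and centred on it Sox2 stood at -2.03. Its strongest WT-labelled loop joined 34647001 to 34658364 with 34750943 to 34766828 by 86 tags. Klf4 had 32 and 4 tags, 13.1 times the share in the WT-labelled list (4.63 to 50.8). Without an FDR limit Klf4 had 34 and 16 tags, a log2 ratio of -2.09. Both lie in the opposite direction to its reads in the RNA-seq libraries of the same labels. The 32 tags lay in 1 loop from 55460603 to 55484119 to the anchor at 55526850 to 55535783, which spans the gene.

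Of all genes with at least 10 tags, 3359 had 0 in the WT-labelled list and 1127 had 0 in the KO-labelled one. The list genes with the largest ratio of KO-labelled to WT-labelled tag shares were Col5a1, Aldh1l1, Nes, Cspg4 and Sox10. Nes, an intermediate filament of neural progenitors (chromosome 3, 87971093 to 87980451), had 0 tags in the WT-labelled and 375 in the KO-labelled list, at least 76.6-fold more by share. Col5a1, a fibrillar collagen, had 0 and 585 tags, the astrocyte enzyme gene Aldh1l1 0 and 408, Cspg4 0 and 335, and Sox10, a factor of oligodendrocytes and neural crest, 0 and 235. Without an FDR limit the WT-labelled list held 14 tags at Nes, 18 at Aldh1l1, 2 at Col5a1 and 0 at Cspg4 and Sox10. The bound at Nes therefore holds under the FDR limit alone: without it Nes had 14 and 465 tags and a log2 ratio of 3.98, and Aldh1l1 had 18 and 471 and a ratio of 3.65. Cspg4 and Sox10 averaged 1.51 and 0.414 CPM in KO-labelled RNA-seq libraries. Pax6 had 0 tags in either list.

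**Figure D3:**
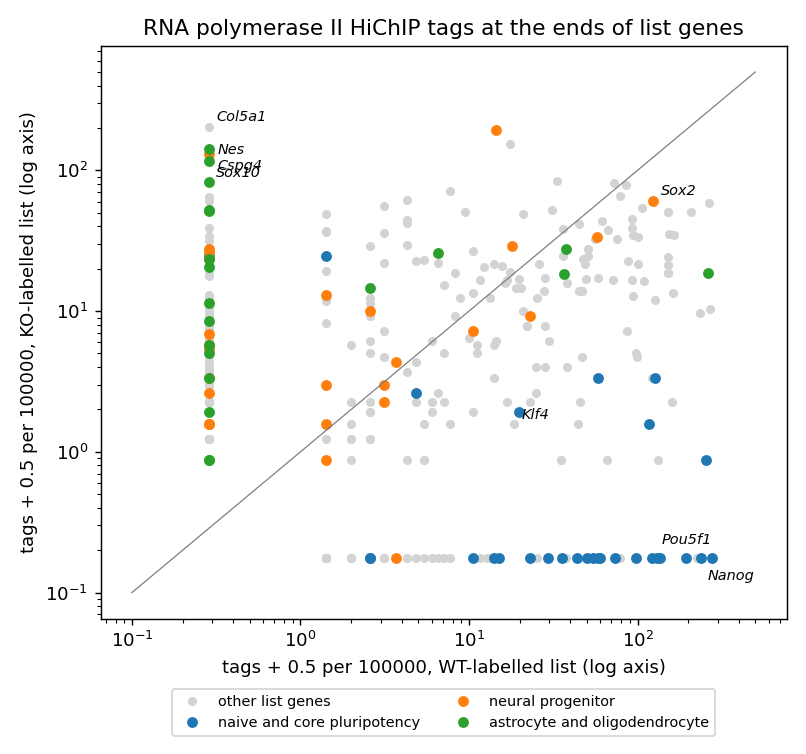
HiChIP tags (plus 0.5 tags, as a share of all tags of the list) of loops touching the ends of list genes, in the WT-labelled list (x, log axis) and the KO-labelled list (y, log axis), 1 point per gene; the line marks equal shares, and points at the left and bottom edges have 0 tags in 1 list. Pluripotency genes such as Nanog (481 and 0 tags) lie below the line, and Nes (0 and 375 tags) and Sox10 (0 and 235 tags) above it.

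Gene lists were set against 10000 random lists of the same size matched on mean tags, as a description of these 2 lists. Summed over pluripotency genes, tags came to 2.24% of all WT-labelled and 0.0619% of all KO-labelled tags. In such sums a loop touching several of the genes counts once for each. The median log2 ratio of tag shares over 27 genes was -7.96 (-5.56 with genes at 0 set to their bounds), below every random list. Another 3 lists lay above the range that held 95% of random lists, and 1 lay on its upper edge. Above it were astrocyte and oligodendrocyte genes (median 5.11 over 16 genes, or 2.60 with bounds, percentile 99.985), Notch genes (4.58 over 14, or 2.60, percentile 99.2) and fibroblast and matrix genes (5.03 over 8, or 2.41, percentile 99.1). On the edge were mesoderm and muscle genes (4.25 over 9, or 1.61, percentile 97.95, with an edge of 4.25). Notch genes fell inside the range with thinned KO-labelled tags or at least 30 tags per gene, fibroblast and matrix genes with at least 30 tags or a pseudocount of 5, and mesoderm genes with a window of 0 bases or a pseudocount of 5. The KO-labelled list gave higher shares to 13 of 19 neural progenitor genes, with a median of 1.96 (1.61 with bounds) at percentile 85.6, within the range of random lists. Centred on the median of all genes with at least 10 tags, 1.01, the neural progenitor median was 0.95. FGF and ERK feedback genes lay at percentile 95.8, and passed above the range with a window of 10000 bases or no FDR limit. Other lists lay within it, primed epiblast at 41.2, glycolysis at 5.97 and neural crest at 4.91. Between these lay the KLF and Sp (15.5), Polycomb (33.2), Wnt (31.8), BMP (83.8), cell cycle (23.7), chromatin architecture (32.1), endoderm (68.6), endothelial (84.9), histone (24.6), p53 (10.1) and stress (9.76) lists. Neural crest genes passed below the range with a window of 10000 bases (median -3.72), and cell cycle genes without an FDR limit (-1.08). The Hox, neuron, trophoblast, forebrain and hindbrain lists had under 5 genes with enough tags. Summed over genes in the same way, Hox genes had 73 tags in the WT-labelled and 0 in the KO-labelled list.

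Loop tags and expression, each as labelled, were positively related across genes. Over 7275 genes with at least 10 tags, the log2 ratio of tag shares correlated with the log2 fold change of expression at Spearman rho = 0.321. This is a correlation across genes, which are not independent replicates, so no p-value is given. Over all 7275 genes the median log2 tag ratio was 0.73, the value to set the following against rather than 0. It was 1.90 (1.36 with bounds) for 2485 genes higher in KO-labelled libraries, -0.097 for 3241 lower genes and 0.77 for 1549 genes not called. For 581 genes at least 4-fold higher it was 4.15 (1.93 with bounds), with 84.3% above 0. For 278 genes at least 4-fold lower it was -4.07 (-3.15 with bounds), with 23.7% above 0.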

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

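Chosen after the data were seen were the fold of at least 2, windows over whole genes, the tags of named genes without an FDR limit, and the pseudocount of 5 tags; the other alternatives given here were planned. Of 111 genes named, 97 kept their call in every setting run on them and 14 lost it in at least 1. The exceptions with a library left out were Dll4, Fas, Foxd3, Gcm1, Hist1h3a, Hspa1a and Sparcl1, and the lone library of the group was then assumed to vary like the other group. Foxd3 reversed to a log2 change of 0.0060 with library size alone, which shifts all genes by 0.21. Leaving out each library gave 5781 to 6235 higher and 5878 to 6038 lower genes, and DESeq2 6270 and 6081. The replicate block gave 6298 and 6112, with a correlation of 0.0153 between same-numbered deviations.

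The stricter tests called fewer genes by construction: testing against a fold of 1.5 gave 4113 higher and 2917 lower genes, and requiring a fold of at least 2 gave 3856 and 1962. Of the 16 lists that passed, 0 did so with the estimated correlation, a version with few residual degrees of freedom and little power here. With fry, which does not compare a list with other genes, 25 lists passed. Without each library, 11 to 16 lists passed.

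Limits on FDR and tags select loops directly, so counts, lengths and tags moved with them. Without an FDR limit the WT-labelled list had 59194 loops, a median length of 107 kb, a mean of 5.45 tags and 23.7% shared, and the KO-labelled list 168426, 92.1 kb, 3.90 and 8.77%. At an FDR of at most 1e-05 the values were 6703, 284 kb, 16.9 and 7.04% for WT and 11429, 250 kb, 11.1 and 4.30% for KO. With at least 5 tags they were 6723, 83.5 kb, 20.3 and 11.0% for WT and 12790, 46.6 kb, 13.97 and 6.36% for KO. With at least 10 tags they were 4519, 33.7 kb, 27.3 and 12.5% for WT and 8459, 21.2 kb, 17.8 and 7.40% for KO. The difference in median length, larger in the WT-labelled list, held in each of these settings. Thinning the KO-labelled tags to the deposited WT-labelled total left 23124 loops of 207 kb and 4.24 tags, 6.27% shared, and 6.22% of WT-labelled loops shared. The FDR of each loop was kept from the full list and not called again, so depth was matched for tags alone. Between 20000 and 2000000 bases the lengths were 374 kb (WT) and 322 kb (KO), the mean tags 6.06 and 3.89, and the KO share 4.62%. Requiring an overlap of 0.5 of the shorter anchor gave 10.9% and 4.43%, and widening anchors by 5000 bases 18.4% and 7.83%.

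For genes, a window of 10000 bases put 2 lists below the range of random lists, and no FDR limit put 4 below it. At least 30 tags per gene left 1 list above it and gave rho = 0.363, windows over whole genes gave rho = 0.354, and a pseudocount of 5 tags left 2 lists above, counting by percentile. The cause was not tested. Depth limits absence: 0 counts allow up to 0.0837 to 0.108 CPM per library.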

Other observations

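Anchors of loops differed between gene groups as deposited, before any limit on tags. Hox genes, which pattern the body axis, had an anchor at 21 of 39 genes in the WT-labelled list and at 0 of 39 in the KO-labelled one. Naive and core pluripotency genes had one at 30 and 14 of 34, and neural progenitor genes at 26 and 32 of 34. Neighbouring genes, such as clustered Hox genes, can share an anchor, so genes are not independent here and no interval is given. The X chromosome held 0.415% of filtered tags in the WT-labelled and 0.106% in the KO-labelled list, chromosome 13 held 4.07% and 1.68%, and chromosome 15 held 3.27% and 5.81%. Over all deposited tags, chromosome 13 held 3.70% and 2.32%.

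The tests of explanations in the paragraphs that follow were chosen after the result was seen, on the same data. The correlation of tag ratio and expression had itself been planned, but not as a test of exchanged labels. Klf4 had reads in the KO-labelled libraries and none in the WT-labelled ones. Reads of other KLF genes are argued against, since the WT-labelled libraries held 20669 Klf2 counts beside 0 for Klf4. WT cells further from pluripotency are argued against for the listed genes, since 25 of 34 pluripotency genes (73.5%) were lower and 9 higher in KO-labelled libraries. The interval of that share, 55.6% to 87.1%, treats genes as independent, which they are not. Whether a KO allele was still transcribed was not tested. A candidate explanation that stays open is an exchange of the RNA-seq labels. The correlation of tag ratio and expression, 0.321, lies above 0, where an exchange could put it below. That holds only if the loop lists are rightly labelled and come from cells in the states of the RNA-seq libraries. Neither is known, so the sign of the correlation cannot decide this. Klf4 loop tags (32 and 4) were higher in the WT-labelled list.

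Few loop tags lay at pluripotency genes in the KO-labelled list, although KO-labelled libraries hold their transcripts: of 25 such genes at 50 CPM or more in both genotypes, 5 had tags there and 21 in the WT-labelled list. A shallower list is argued against, since 78.7% of all genes at that level had tags in the KO-labelled and 69.9% in the WT-labelled list. Missing anchors stay open. As deposited, 14 of 34 pluripotency genes had an anchor in the KO-labelled list and 30 in the WT-labelled one. Over the 14 pluripotency genes with an anchor the median log2 ratio was -2.9985 (interval -5.22 to 1.22). That median cannot speak for the genes without an anchor. Loop lists and RNA-seq libraries from cells in different states also stay open. The share under 1 CPM in KO-labelled libraries was taken over list genes, other than pluripotency genes, with tags in the KO-labelled list alone. It was 25.8% (17 of 66, interval 15.8% to 38.0%), against 0 of 15 (at most 21.8%) for the WT-labelled list. The intervals overlap, but overlap is not a test of a difference, and none was run. Among all such genes with at least 10 tags in the KO-labelled list the share was 18.0% (36 of 200, interval 12.94% to 24.04%). For the WT-labelled list it was 13.97% (19 of 136, interval 8.63% to 20.95%).

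Genes of chromosome 8 were higher in KO-labelled libraries, with a median log2 fold change 0.28 above that of all genes (0.275 to 0.294 over pairs of libraries). Whether the whole chromosome was gained stays open. Its lowest bin, at 20 to 40 Mb, had a median of -0.084 (interval -0.311 to 0.116). That bin was picked as the lowest, and its interval covers the spread of genes within the bin alone. Bins of other chromosomes ran from -0.57 to 0.67, so a single low bin cannot decide this. The bins at 60 to 80 and 80 to 100 Mb had medians of 0.57 and 0.49, ranks 2 and 5 of 135, beside 0.67 at 0 to 20 Mb of chromosome 14, -0.57 at 160 to 180 Mb of chromosome 2 and -0.53 at 40 to 60 Mb of chromosome 11. A gain of that part could account for this and stays open: its loop tag share differed by -0.20 and 0.065 (log2), but those lists are not known to come from the same cells. Chromosome 8 as a whole held 4.14% of all deposited WT-labelled and 5.73% of KO-labelled tags (3.88% and 5.50% of filtered tags).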
